A study of Homo sapiens with 2 samples.

How the data were processed

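Gene expression was measured in HT29 cells, a human colorectal adenocarcinoma line used as a model of intestinal epithelium. The cells had shared a patterned surface with Jurkat cells, a human leukaemic T cell line, that were either uninfected or infected with HIV. Per the series' design text, HT29 cells were cut out by laser microdissection and their RNA was hybridised to Affymetrix U133 Plus 2 arrays. Per the labels' protocols, total RNA was extracted with an RNeasy kit and biotinylated cRNA was prepared from it. There were 2 samples, 1 per co-culture, so no comparison has a replicate check and no p-value across genes is given.

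The deposited table holds 1 intensity per probe set and sample for 54675 probe sets, of which 62 are the manufacturer's controls. The intensity values were made by the authors with a summarisation and scaling method that is not given in the sources used here. The values were taken as linear because they are right-skewed and reach 29251, and no value was below 1, which 12 probe sets held exactly in each sample. The quantiles of the 2 columns differed, so the columns were not quantile normalised to each other. No detection calls, background estimates or probe-level values were used here, so a dim probe set cannot be given a detection p-value.

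All choices in this paragraph were made before the data were examined. Intensities were converted to log2 and used as deposited, because the column medians differed by only 0.06 on the log2 scale, below the limit of 0.5 that would have called for centring. A probe set counted as measured when its mean log2 value was at or above the median of all probe sets, which was an intensity of 19.0. Genes were named through the platform annotation and a reference gene table: 41091 of the probe sets paired with 1 gene symbol, 1801 with several, and 11721 were not listed with a gene and are unnamed here. Each gene took its measured probe set with the highest mean, which left 13243 genes. Of 64 named genes with 2 or more measured probe sets, 21 had probe sets of both signs. Differences are given as HIV-infected minus uninfected co-culture, and a gene was counted as higher or lower when it differed at least 2-fold. The 25 gene lists named 653 genes, of which 436 were measured. The median log2 difference of each list was set against 10000 random lists of the same size, matched on mean level in 20 bins, and the percentile is a description of these 2 samples. No coordinates are given, because the files name no genome build.

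The rule for named genes had 3 parts. The first took the 10 highest and 10 lowest mean log2 differences among genes with 2 or more measured probe sets that all moved the same way. The second took the 5 highest and 5 lowest among genes with exactly 1 measured probe set. The third took up to 4 measured members with the largest differences from each list. Uncharacterised loci were skipped in the first and second parts. Other genes named below were chosen after their values were seen, and the text says where.

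A background ceiling was chosen after the data were seen. It is 30.44, the highest intensity on either array among 27 control probe sets for bacterial transcripts (dap, lys, phe, thr and trp), which ranged from 2.99 to 26.19 with uninfected and from 2.38 to 30.44 with HIV-infected Jurkat cells. Where the dimmer value of a gene lay below this ceiling, the fold is given as "at least", the brighter value over the ceiling. With a single array per co-culture the number of arrays, not the depth, limits the precision.

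Other settings tried were centring on the median of measured probe sets, quantile normalisation, no filter on dim probe sets, only probe sets at or above the 75th percentile of mean level, 32 added to each intensity before log2, the mean of all measured probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at, which can match several transcripts, and thresholds of 1.5-fold and 3-fold. Chosen after seeing the data were raising all values to the background ceiling, scaling on the 18 bioB, bioC, bioD and cre hybridisation controls, and matching random lists on the level in the uninfected co-culture. An alternative value of a gene was called close when it moved by less than 0.94, the pooled SD of log2 differences among measured probe sets of a gene, and that of a list when it stayed inside the 95% bootstrap interval of its median over members.

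The scripts were tested on simulated data in which 200 genes of this comparison were changed, with noise of 0.5 on the log2 scale. Over 12990 genes, the 2-fold rule recovered 80.5% of genes changed 2.83-fold and 100% of those changed 4-fold, and it called 4.64% of unchanged genes. The simulated noise was smaller than the SD of 0.94 among probe sets of a gene in the data. These shares therefore test the scripts and are not error rates of the comparison. Of 200 unchanged random lists, 4.5% lay outside the central 95% of their random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.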

Results

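HT29 cells were profiled from 2 co-cultures on 1 array each, 1 with uninfected and 1 with HIV-infected Jurkat cells. The series asks how the epithelial cells' transcripts differ when the neighbouring T cells carry HIV. Most probe sets were dim on both arrays. The median intensity was 18.8 with uninfected and 19.5 with HIV-infected Jurkat cells, and 26.9% and 26.0% of the 54613 probe sets that are not controls lay above the highest bacterial control, 30.44. The bright end differed: 2448 probe sets exceeded 100 with uninfected Jurkat cells and 1049 did with HIV-infected ones. There was 1 sample per group throughout, so all differences below are between these 2 samples and no error between replicates can be given.

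With HIV-infected Jurkat cells as neighbours, the HT29 sample had lower levels of ribosomal protein, glycolytic, heat shock, KRT18 and TUBA1B transcripts, many of them more than 4-fold. The higher genes were fewer and dim. A loss of mRNA-derived signal whatever the gene, such as a failed amplification of this sample, cannot be told apart from a loss in chosen genes. The median difference fell with the uninfected level among 2213 genes with 2 or more probe sets above background with uninfected Jurkat cells. It was 0.04 on the log2 scale for genes read there at 30.44 to 60 and -2.46 for those over 500. These genes were chosen and grouped by the uninfected level, and those near background had little room to fall. Part of the gradient can therefore be built in. The share at least 2-fold lower was 70.1% at 250 to 500 and 60.6% over 500. Among 1849 genes chosen in the same way with HIV-infected Jurkat cells, the median was 0.06, with 246 lower and 83 higher. RPL10A, a ribosomal protein gene, was 25.7-fold lower and LDHA, a glycolytic enzyme gene, at least 14.5-fold lower. Of 21 measured interferon-stimulated genes, none was at least 2-fold higher. Of these, 8 lay below the background ceiling on both arrays, so the absence of an interferon response is not shown. Of the 2448 probe sets over 100 with uninfected Jurkat cells, 766 lay below the background ceiling with HIV-infected ones. Of 13243 measured genes, 1956 were at least 2-fold lower and 620 at least 2-fold higher with HIV-infected Jurkat cells. Quantile normalisation gave 1568 lower and 1211 higher, and scaling on the hybridisation controls gave 2773 lower and 231 higher, so the balance between the directions depends on the scaling. The lower genes were the brighter ones: 839 of them exceeded 100 on their brighter array, against 62 of the higher genes. Among the 908 lower genes with a second measured probe set, 361 had that probe set at least 2-fold lower as well (39.8%, against 17.6% of all second probe sets). Among 176 higher genes with one, 17 had it at least 2-fold higher (9.66%, against 4.45%). With values under the background ceiling raised to it, 1376 genes were lower and 178 higher.

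Housekeeping transcripts measured by control probe sets were also lower in the co-culture with HIV-infected cells. The 3' probe set of ACTB, which encodes beta-actin, read 1651 with uninfected and 108 with HIV-infected Jurkat cells, and that of GAPDH, a glycolytic enzyme, read 3582 and 1213. The 3' over 5' intensity ratio of GAPDH was 16.0 with uninfected and 36.2 with HIV-infected Jurkat cells, whereas that of ACTB was 6.88 and 0.833. The control probe sets for Alu repeats and ribosomal RNA differed by less than 2-fold. The Alu probe set read 10537 and 9967, the 3' probe set of 18S ribosomal RNA 11245 and 11039, and its 5' probe set 4340 and 5844. The 18 hybridisation controls, bacterial and phage transcripts added to the labelled sample, were higher with HIV-infected Jurkat cells by a median log2 difference of 0.42, with a range of 0.04 to 0.65.

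**Figure D1:**
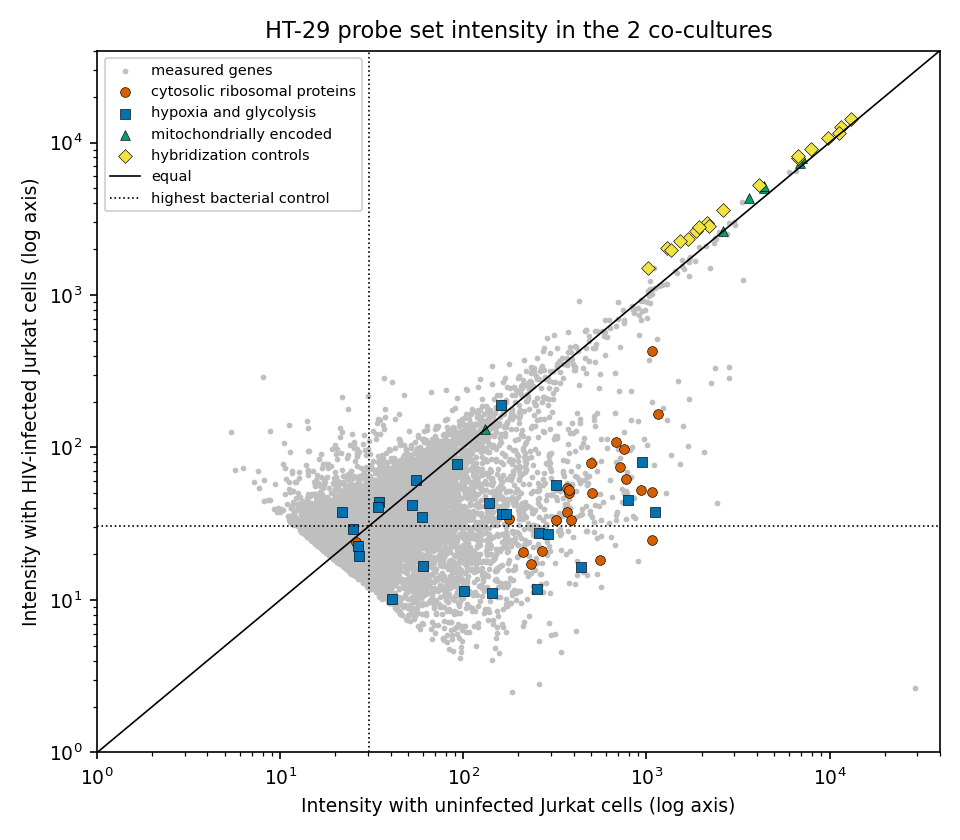
Probe set intensity of each measured gene with uninfected (x axis) and HIV-infected (y axis) Jurkat cells, both on log axes, 1 array each; coloured points mark gene groups and hybridisation controls, and dotted lines the highest bacterial control, 30.44. Ribosomal protein genes and many hypoxia and glycolysis genes lie below the line of equality, while mitochondrially encoded genes and hybridisation controls lie near it.

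Of the 10 genes with the lowest mean differences across several probe sets, RPL10A, RPS4X and RPL37A encode ribosomal proteins. RPL10A read 1284 with uninfected and 49.9 with HIV-infected Jurkat cells, 25.7-fold lower. RPS4X was 21.9-fold lower, at 2053 and 93.6, and RPL37A was 19.5-fold lower, at 1518 and 77.9. EEF1A1, the translation elongation factor that delivers tRNA to the ribosome, was 16.5-fold lower at 1677 and 102. TUBA1B, an alpha-tubulin, was 25.05-fold lower at 865 and 34.5, and all 5 of its measured probe sets were lower. FASTK, a kinase family member with roles in RNA processing, was 23.8-fold lower at 843 and 35.4. ANXA2, a calcium-dependent membrane-binding protein, was at least 16.9-fold lower at 514 and 27.9. TNIP2, an inhibitor of NF-kB signalling, GTF3A, the transcription factor for 5S ribosomal RNA genes, and ATP5IF1, the inhibitor of mitochondrial ATP synthase, lay below the background ceiling with HIV-infected Jurkat cells and were at least 7.06, 6.34 and 5.66-fold lower. Probe sets of a family such as the ribosomal proteins or tubulins can share signal with near-identical copies and pseudogenes.

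Among genes with a single measured probe set, the lowest was SV2B, a synaptic vesicle protein. That probe set read 29251 with uninfected Jurkat cells, the highest value on that array, and 2.64 with HIV-infected ones, at least 961-fold lower. No probe-level values were used here to check that reading for a defect of the probe set. The other SV2B probe sets read 2.59 and 8.79 with uninfected Jurkat cells, both under the ceiling, and were not counted as measured. SNRPA, a U1 small nuclear ribonucleoprotein component, read 410 and 6.23, at least 13.5-fold lower. SNHG19, a host gene of small nucleolar RNA, was at least 11.2-fold lower, BICDL2, a dynein adaptor, at least 10.4-fold lower, and ATP6V0B, a subunit of the vacuolar proton pump, at least 6.03-fold lower.

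Genes higher with HIV-infected Jurkat cells were dimmer. ZC3HAV1, the zinc finger antiviral protein, read 36.8 with uninfected and 285 with HIV-infected Jurkat cells on its brighter probe set, 7.75-fold higher, and 18.3 and 32.9 on its second measured probe set. TIMM8B, a mitochondrial import chaperone, read 21.7 and 215 on one probe set, at least 7.05-fold higher, but 32.3 and 34.2 on the other. BRD10 was at least 4.01-fold higher at 24.5 and 122, MARK4, a microtubule affinity regulating kinase, 2.56-fold higher at 44.4 and 113, and DCN, the matrix proteoglycan decorin, at least 2.57-fold higher at 10.3 and 78.2. LYPD8, a colonic epithelial protein that restrains flagellated bacteria, read 19.2 and 43.1 on its brighter probe set and 3.84 and 178 on the other. GPR12, an orphan receptor, read 18.5 and 54.6 on its brighter probe set. The brighter probe sets of ACKR5, ACACB (acetyl-CoA carboxylase beta) and RAPGEF6 differed by less than 2-fold, at 20.2 and 26.3, 161 and 199.6, and 25.7 and 32.1. Their places among the 10 highest came from their dimmer probe sets.

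The 5 highest genes with a single measured probe set were below the ceiling with uninfected Jurkat cells. FOXJ1, a regulator of motile cilia, read 11.2 and 139.7, at least 4.59-fold higher. TCTA read 8.77 and 129, at least 4.24-fold higher, CRISP1 was at least 2.33-fold higher and ATP6AP1L at least 2.40-fold higher. COPB1, a coatomer subunit, read 5.37 and 126 on its measured probe set, at least 4.15-fold higher, but its other probe sets, which were not counted as measured, went the other way, from 40.4 to 3.68 and from 31.7 to 4.49.

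**Figure D2:**
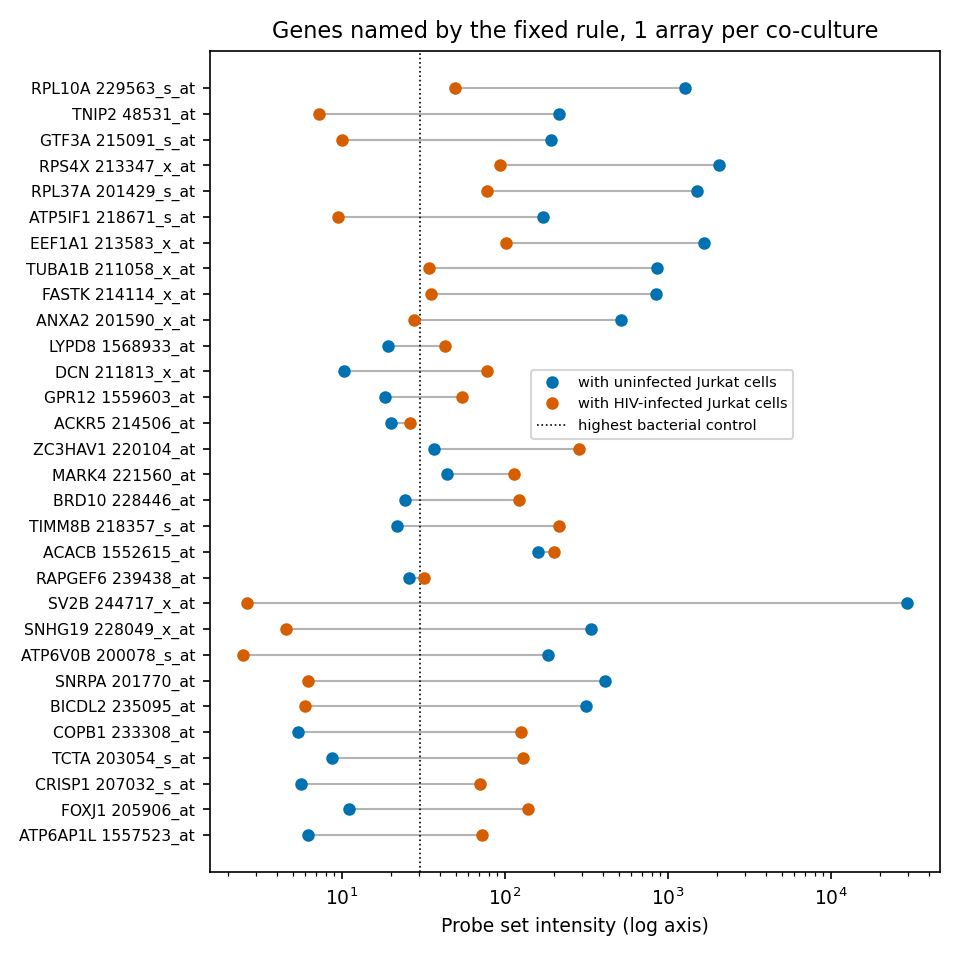
Intensity (x axis, log scale) of the probe set chosen for each gene named by the first and second parts of the fixed rule, with uninfected (blue) and HIV-infected (orange) Jurkat cells, 1 array each. The 15 lower genes read 172 or more with uninfected Jurkat cells, and 14 of the 15 higher genes read under 45 there.

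Cytosolic ribosomal protein genes were lower as a group. Of 23 measured, 22 were at least 2-fold lower and none higher, with a median log2 difference of -3.26, below all 10000 random lists. RPS16 read 1070 with uninfected and 24.8 with HIV-infected Jurkat cells, at least 35.2-fold lower, RPL27 was at least 18.2-fold lower, and RPS28 and RPS19 were 21.1-fold and 17.7-fold lower on their brightest probe sets. Another measured probe set of RPS28 read 39.0 and 34.5, above the ceiling on both arrays. The other measured probe sets of RPS19 read 57.1 and 44.2, and 214 and 35.9. The probe set of RPS28 left without the _x_at and _s_at sets read 28.1 and 41.2, the first below the ceiling, and the median of the list was then -1.38. Against random lists matched on the uninfected level, the list stood at the 0.28 percentile. Those random lists had a median of -1.88, against -0.21 for lists matched on mean level. Much of the ribosomal fall was therefore shared by genes as bright with uninfected Jurkat cells.

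Genes of hypoxia and glycolysis were also lower: 15 of 26 at least 2-fold lower, none higher, with a median log2 difference of -1.93 and below all 10000 random lists. NDRG1, a hypoxia-induced gene, read 1112 and 37.6, 29.6-fold lower. LDHA, lactate dehydrogenase A, was at least 14.5-fold lower at 441 and 16.4, P4HA1, a collagen prolyl hydroxylase subunit, at least 8.29-fold lower, and ALDOA, aldolase A, 17.4-fold lower at 794 and 45.6. Its median was -1.22 without _x_at and _s_at probe sets and -1.09 with 32 added to each intensity. This list stood at the 0.11 percentile of random lists matched on the uninfected level, which had a median of -0.45.

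Heat shock genes had a median log2 difference of -2.32 at the 0.11 percentile, with 6 of 9 at least 2-fold lower. HSP90AA1, an inducible cytosolic chaperone, read 628 and 31.8, 19.7-fold lower. HSP90AB1 was 9.11-fold lower and HSPD1, the mitochondrial chaperonin, 7.02-fold lower. Targets of WNT signalling and crypt progenitor markers had a median of -1.54 at the 0.08 percentile, with 8 of 12 at least 2-fold lower. EPHB3 was at least 4.65-fold lower, RNF43, a ubiquitin ligase that restrains WNT receptors, at least 5.62-fold lower, and MYC 4.28-fold lower at 186 and 43.4. CD44 was 3.68-fold lower on its brightest probe set, while its measured probe sets outside the _x_at and _s_at sets went both ways, 1 reading 54.9 and 23.3 and the other 32.8 and 39.1. Without _x_at and _s_at probe sets the heat shock median was -0.69 and the WNT median -0.89. With no filter on dim probe sets they were -1.16 and -0.57, and the heat shock median was -1.13 with probe set means and -1.39 with 32 added. Matched on the uninfected level, the heat shock list stood at the 9.44 percentile and the WNT list at 3.95, so neither was then below the 2.5 percentile. The random lists so matched had medians of -1.23 for heat shock and -0.55 for WNT.

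Stress, metabolic and cell cycle lists held members that were lower. Of 21 unfolded protein and integrated stress response genes, 5 were at least 2-fold lower and none higher (median -0.46, 0.74 percentile). DDIT4, an inhibitor of mTOR, read 407 and 12.8, at least 13.4-fold lower, and ATF4, the transcription factor of the integrated stress response, was 5.12-fold lower. Of 26 nuclear-encoded oxidative phosphorylation genes, 9 were lower and 1 higher (median -0.48, 0.32 percentile). COX7C was at least 7.38-fold lower and NDUFV1 at least 6.55-fold lower, although another measured probe set read 31.7 and 32.9 for COX7C and 36.0 and 33.4 for NDUFV1. The median of this list was 0.0554 over the 19 genes left without _x_at and _s_at probe sets, 5 of which lay below the ceiling on both arrays. Of 16 cholesterol genes, 6 were lower (median -0.48, 2.05 percentile), among them HMGCS1, which makes HMG-CoA, at least 7.73-fold. In the S phase list 4 of 16 were lower (median -0.39, 1.69 percentile), with the flap endonuclease FEN1 at least 6.39-fold lower. In the G2 and M phase list 6 of 15 were lower (median -0.46, 1.98 percentile), with the proliferation marker MKI67 3.22-fold lower at 398 and 124. With the background floor, 4 stress response, 6 oxidative phosphorylation, 4 cholesterol, 4 S phase and 3 G2 and M phase genes were at least 2-fold lower. Over the other settings the medians ranged from -0.30 to -0.88 for the stress response, -0.29 to -1.08 for cholesterol, -0.19 to -0.80 for S phase and -0.17 to -0.88 for G2 and M phase genes. None of these 5 lists was below the 2.5 percentile of random lists matched on the uninfected level.

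**Figure D3:**
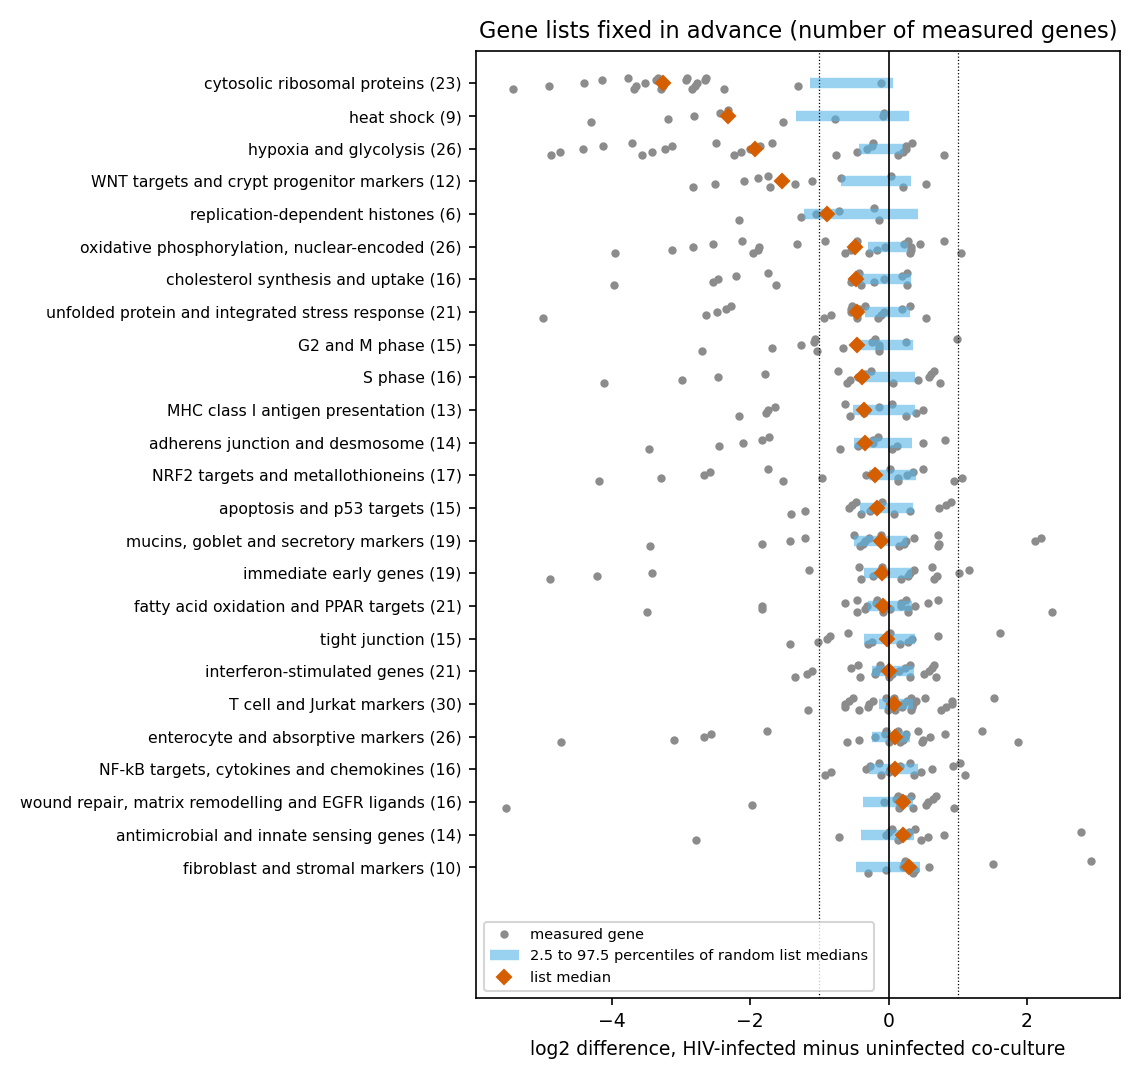
Log2 difference (x axis, HIV-infected minus uninfected co-culture) of each measured gene (grey) in the 25 lists fixed in advance, with the list median (orange) and the central 95% of 10000 random list medians matched on mean level (blue). The medians of 9 lists lie below that range and none lies above it.

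Barrier and epithelial genes were mixed. In the tight junction list 2 of 15 were at least 2-fold lower and 1 higher (median -0.02, 29.3 percentile), but none was either with the background floor. OCLN, the junction protein occludin, read 68.7 and 37.0, under 2-fold, and PARD6B, a polarity protein, 36.1 and 13.4. CGN, cingulin, read 54.8 and 26.9 on one probe set and 35.1 and 39.7 on another. CLDN4 read 13.8 and 41.9 on one and 36.0 and 15.2 on another, so the directions of both genes were not settled. In the adherens junction and desmosome list 5 of 14 were lower and none higher (median -0.33, 6.47 percentile). CDH1, E-cadherin, read 386 and 70.6, 5.48-fold lower, EPCAM, the epithelial adhesion molecule, 118 and 10.8, at least 3.89-fold lower, and CTNNA1, alpha-catenin, was 4.32-fold lower, while its measured probe set outside the _x_at and _s_at sets read 16.5 and 22.6, both below the ceiling, and a further one 29.8 and 33.3. Of 26 enterocyte markers, 5 were lower and 2 higher (median 0.09, 51.4 percentile). The epithelial keratins KRT18 and KRT19 were 8.55-fold and 5.93-fold lower, at 1294 and 151 and at 749.8 and 127, and LGALS4, an intestinal galectin, was at least 4.95-fold lower. Among 19 mucin and secretory genes, 4 were lower and 2 higher (median -0.11, 31.0 percentile). The sign of that median was not settled, since it was 0.44 with quantile normalisation, 0.06 with no filter and 0.19 without _x_at and _s_at probe sets. MUC1 read 256 and 23.3, at least 8.40-fold lower, and MUC17, a membrane mucin, 47.6 and 219, 4.61-fold higher, although its second measured probe set read 46.7 and 32.7. In the wound repair list 2 of 16 were lower and none higher (median 0.21, 82.8 percentile), and ITGA6, a laminin-binding integrin, was at least 18.6-fold lower.

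Lists of antiviral and inflammatory genes did not stand apart from random lists. Of 21 interferon-stimulated genes, none was at least 2-fold higher and 3 were lower (median 0.0029, 26.4 percentile). With the background floor 1 was lower, and 8 of the 21 lay below the ceiling on both arrays. BST2, the restriction factor tetherin, read 90.4 and 35.6, 2.54-fold lower, and IFITM1 34.3 and 55.3. Of 16 NF-kB targets, cytokines and chemokines, 2 were higher and none lower (median 0.09, 41.7 percentile), and both lay near background: IL6 read 15.7 and 32.1, and TNFAIP2 18.5 and 39.7 on one probe set but 63.3 and 7.2 on another. Of 13 MHC class I genes, 4 were lower (median -0.36, 6.70 percentile). The median was 0.05 without _x_at and _s_at probe sets and -0.69 with probe set means. B2M and TAPBP, named after their values were seen, were counted as under 2-fold, with log2 differences of 0.50 and -0.55. The lowest of their measured probe sets stood at -5.01 and -3.74, so their directions were not settled. HLA-C was 4.49-fold and HLA-B 3.40-fold lower, and these near-identical genes can share signal. LYZ, lysozyme, was 6.91-fold lower at 394 and 57.1 among 14 antimicrobial and sensing genes, in which TLR3, a sensor of double-stranded RNA, read 10.6 and 73.1 (median 0.21, 81.6 percentile).

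The remaining lists gave medians within the range of random lists. Fatty acid oxidation and PPAR targets had 3 lower and 1 higher of 21 (median -0.08, 16.9 percentile), with ETFB, an electron transfer flavoprotein, at least 8.37-fold lower and PLIN2, the lipid droplet protein perilipin, read at 16.3 and 84.0, at least 2.76-fold higher. NRF2 targets and metallothioneins had 6 lower and 1 higher of 17 (median -0.20, 5.48 percentile), with GPX2, a gastrointestinal glutathione peroxidase, at least 5.86-fold lower. Immediate early genes had 4 lower and 2 higher of 19 (median -0.10, 18.5 percentile), with IER3 at least 14.9-fold lower. Apoptosis genes had 2 lower of 15 (median -0.17, 12.5 percentile, and 0.29 with quantile normalisation), with the death receptor caspase CASP8 at least 2.16-fold lower. Replication-dependent histones had 3 lower of 6 (median -0.88, 5.51 percentile). With no filter on dim probe sets the medians were 0.10 for fatty acid oxidation, 0.06 for NRF2 targets, 0.18 for immediate early genes and -0.19 for histones, and that of tight junction genes was 0.17 with quantile normalisation. For 5 genes given above as lower, another measured probe set was not lower and lay below the ceiling on both arrays: CASP8 (20.9 and 21.8), MUC1 (19.6 and 19.8), EPHB3 (19.8 and 21.5), RPS16 (27.4 and 29.6) and HSPD1 (18.1 and 27.8).

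Of 30 T cell and Jurkat markers, 1 was at least 2-fold higher and 1 lower (median 0.08, 32.4 percentile). The background ceiling was exceeded by 10 of them with uninfected and 14 with HIV-infected Jurkat cells. CD3D, a component of the T cell receptor complex, read 70.1 and 57.8, RAG1, the recombinase, 24.3 and 69.6, and CD7 47.4 and 89.8. Of 10 stromal markers, 2 were higher and none lower (median 0.29, 85.0 percentile), namely DCN and ACTA2, smooth muscle actin. ACTA2 read 23.4 and 66.6 on one measured probe set and 36.7 and 28.3 on the other, so its direction was not settled. The ceiling was exceeded by 3 and 6 of the 10. The positive list medians given here, the highest being 0.29, became negative when the arrays were scaled on the hybridisation controls, which lowers every log2 difference by 0.42. CD3D was named after its values were seen.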

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

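The tests of the hybridisation controls, the 3' and 5' probe sets, the other probe sets of bright genes, the mitochondrially encoded genes, saturation and the T cell markers were chosen only after the result was seen.

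Abundant nuclear transcripts were lower in the sample with HIV-infected Jurkat cells. A difference in hybridisation or scaling between the arrays is argued against by the hybridisation controls, whose median log2 difference was 0.42 upwards while that of the ribosomal protein genes was -3.26. Degraded RNA cannot be told apart from other losses, because the 3' minus 5' gap changed by 1.18 in GAPDH and by -3.05 in ACTB (mean -0.94, log2 scale). A loss of mRNA-derived signal whatever the gene, such as a failed amplification or labelling of 1 sample, cannot be told apart from a loss in chosen genes: among 2213 genes with 2 or more probe sets above background with uninfected Jurkat cells, 1 of 17 lists (5.88%), that of cholesterol genes, stood outside the central 95% of lists matched on the uninfected level, but these lists held only 4 to 8 genes. Over all measured members, the ribosomal protein list (0.28 percentile) and that of hypoxia and glycolysis (0.11) stood below the central 95% of such matched lists, and the 7 mitochondrially encoded genes, with a median of 0.16, were not lower, though whether their signal came from mRNA was not tested; a response of the epithelial cells to infected neighbours stays open and untested, since each co-culture was sampled once.

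Some bright probe sets were almost equal on both arrays. Of nuclear probe sets with 1 gene symbol that read 500 or more with uninfected Jurkat cells, 75 differed by less than 0.5 on the log2 scale, and 84% of them were _x_at probe sets, which can match several transcripts, against 43.8% of probe sets of that brightness that were at least 2-fold lower and 7.70% of all probe sets. The 200 other probe sets of the same genes had a median of 19.5 with uninfected Jurkat cells, below the background ceiling, whereas the 151 other probe sets of genes bright and at least 2-fold lower had a median of 56.4. A template other than the spliced mRNA of the named gene, such as repeats in nuclear RNA or genomic DNA, is a candidate source, which these data do not separate. Saturation did not hold all probe sets over 500 equal, because 137 of them were at least 2-fold lower. The levels of the 75 and the 137 were not matched, and a saturated probe set can still read lower when its target falls far. Saturation of the 75 therefore stays open.

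The genes higher with HIV-infected Jurkat cells were mostly dim. Of 40 measured olfactory receptor genes, which a colon line should lack, 3 were at least 2-fold higher (7.5%, exact 95% binomial interval 1.57% to 20.4%), against 4.67% of other genes. Their median log2 difference was 0.37 (-0.04 with scaling on the hybridisation controls). The interval reached the share of other genes, but with 40 genes even none higher would have left an upper bound of 8.81%. This test could therefore not have argued against scatter. Whether scatter and drift of dim probe sets supply many of the higher genes was not settled. None of the 40 was at least 2-fold lower (upper exact bound 8.81%), against 14.8% of other genes. Carried-over Jurkat RNA stays open: T cell and Jurkat markers stood at the 32.4 percentile of random lists with members going both ways, RAG1 (24.3 and 69.6) at least 2-fold higher, PTPRC (28.7 and 12.8, both below the ceiling) at least 2-fold lower and the others, such as CD7 (47.4 and 89.8) and CD3D (70.1 and 57.8), under 2-fold, and 13 of the 30 lay below the ceiling on both arrays. Single genes such as ZC3HAV1 stay open.

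In data outside the comparisons, 6406 measured probe sets paired with no single gene. Above the background ceiling, 342 of these were at least 2-fold higher with HIV-infected Jurkat cells and 753 at least 2-fold lower. Among measured genes, whatever their level, 4.68% were at least 2-fold higher and 14.8% lower. Among higher probe sets not listed with a gene, the one brightest with HIV-infected Jurkat cells read 203.6 with uninfected and 534 with HIV-infected Jurkat cells.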

How the results depend on the processing

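The background floor, scaling on the hybridisation controls and matching on the uninfected level were chosen after seeing the data. No paired analysis was possible because each co-culture had 1 sample, and for the same reason no sample could be left out. The 1956 lower genes became 1942 with median centring, 1568 with quantile normalisation, 2622 with no filter, 1415 above the 75th percentile of level, 1844 with probe set means, 1376 with the background floor and 2773 with scaling on the hybridisation controls, and moved by over 1.5 times to 1279 with 32 added to each intensity, to 1225 without _x_at and _s_at probe sets and to 1286 at 3-fold. The 620 higher genes were less stable: 643 with centring, 515 with probe set means and 553 without _x_at and _s_at probe sets, but 1211 with quantile normalisation, 1593 with no filter, 252 above the 75th percentile of level, 114 with 32 added, 178 with the floor, 231 with scaling on the controls, 2110 at 1.5-fold and 165 at 3-fold. These counts are not shares of the same total. Against 13243 measured genes, 10077 were measured without _x_at and _s_at probe sets, 7767 above the 75th percentile of level and 19775 with no filter. The share of higher genes among those called was 24.1%, and ranged from 7.69% with scaling on the controls to 43.6% with quantile normalisation. Scaling on the controls moved every gene by 0.42 on the log2 scale, and quantile normalisation put the median gene at 0.24 in place of 0.09. The 9 lists below the 2.5 percentile became 6 to 11 under the other settings, but 2 when random lists were matched on the uninfected level. The ribosomal median of -3.26 was -2.60 with quantile normalisation, -2.51 with 32 added, -2.77 with probe set means, -1.38 without _x_at and _s_at probe sets and -3.68 with scaling on the controls. The heat shock median ranged from -0.69 to -2.74 and that of hypoxia and glycolysis from -1.09 to -2.34. Without _x_at and _s_at probe sets, the sign changed for the oxidative phosphorylation list (0.0554), CTNNA1 (0.45), COX7C (0.0554), COX5A (0.23), CD44 (0.25) and RPS28 (0.55); it changed for CGN with quantile normalisation (0.30) and for TNFAIP2 with 32 added (-1.28) and with probe set means (-1.02). The remaining CTNNA1 and COX5A probe sets lay below the ceiling on both arrays and a second CD44 probe set stayed lower, so no reversed direction is shown for these genes. Medians inside the random range changed sign too: with quantile normalisation for tight junction (0.17), apoptosis (0.29), fatty acid (0.08) and mucin (0.44) lists, with no filter for NRF2 (0.06), fatty acid (0.10), mucin (0.06) and immediate early (0.18), with probe set means for immediate early (0.04), without _x_at and _s_at for MHC class I (0.05), tight junction (0.0006), fatty acid (0.02) and mucin (0.19), and with scaling on the controls for 7 positive medians. The cause was not tested. Over 129 named genes and all alternatives, 926 of 1068 values were close to the reported one. Part of this count was fixed in advance. Median centring and scaling on the controls shifted every gene alike, by less than the limit for close. With no filter or above the 75th percentile of level, a gene kept its probe set and value. Of 129 genes, 76 were close with 32 added, 87 with the floor and 103 with probe set means. Quantile normalisation left 119 close, 7 moved and 1 of changed sign, and leaving out _x_at and _s_at probe sets left 56, 8 and 5. Of 13 gene values with a changed sign, those of MDM2 with probe set means (-0.22) and of ACKR5, ACACB, RAPGEF6 and TAGLN with scaling on the controls were of genes reported at under 2-fold. Dim signal limits the rest: 3280 of the 13243 measured genes lay below the ceiling on both arrays.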

Other observations

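The gene families in this part were chosen after the data were seen, and none was set against random lists matched on the uninfected level. Of 19 measured genes with symbols that begin with HNRNP, RNA-binding proteins of the nucleus and 1 pseudogene, 14 were at least 2-fold lower with HIV-infected Jurkat cells and none higher. Their median log2 difference was -2.06, and it was negative under every scaling tried (-1.25 with quantile normalisation, -2.48 with scaling on the hybridisation controls). Without _x_at and _s_at probe sets, 7 of 13 were lower (median -1.47). Their median uninfected level was 7.22 on the log2 scale, within 120 to 250. Of the 2213 genes with 2 or more probe sets above background there, 66.8% of those read at 120 to 250 were lower (median -1.59). Much of the fall was thus shared by genes as bright. HNRNPA2B1 read 826 and 64.4, and HNRNPDL 566 and 82.1. Genes with symbols that begin with EIF, most but not all of which encode translation initiation factors, had 19 lower and 1 higher of 36 (median -1.03). The higher one was EIF4EBP1, which encodes a repressor that binds eIF4E, at 17.8 and 42.7, at least 1.40-fold. With the background floor 16 were lower and 0 higher. Without _x_at and _s_at probe sets, 7 of 23 were lower (median -0.67). Measured proteasome subunits had 12 lower and 1 higher of 27 (median -0.86), with PSMB7 at 287 and 19.7. With the background floor 8 were lower (median -0.50), and without _x_at and _s_at probe sets 9 of 20 were (median -0.59). Tubulin genes, 1 of them a pseudogene, had 6 lower of 11 (median -1.03), and 2 lower with quantile normalisation. Other families tried were gathered by symbol and hold some genes of other kinds. The annexin set had a median of -0.14, with 5 lower and 2 higher of 16, at the 16.1 percentile of random lists matched on mean level. It includes ANXA2R and ANXA2 pseudogenes, with ANXA2R-AS1 (13.1 and 30.3, both below the ceiling) among the higher and the pseudogene ANXA2P2 among the lower. Serine and arginine rich splicing factors (-0.46, 4 lower of 9) lay at the 11.8 percentile and genes with EEF symbols (-0.80, 3 lower of 7) at 7.10. The 3 lower were the elongation factors EEF1A1, EEF1D and EEF2, while EEF1A2 was not lower. EEF2K, EEF1AKMT2 and EEF2KMT encode modifying enzymes. Without _x_at and _s_at probe sets, none of 3 EEF genes was lower (median 0.29). Genes with symbols of the vacuolar ATPase (-0.26, 5 lower and 1 higher of 21) lay at the 1.14 percentile, with a median of 0 with the background floor. The higher one was ATP6AP1L, which, like the noncoding ATP6AP1-DT also counted, is not a subunit gene.

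The 7 measured mitochondrially encoded genes differed by less than 2-fold. The respiratory complex I subunit ND4 read 6876 with uninfected and 7341 with HIV-infected Jurkat cells, the cytochrome oxidase subunit COX1 2609 and 2640, and the ATP synthase subunit ATP6 4387 and 5004. Their median log2 difference was 0.16, and -0.25 with scaling on the hybridisation controls. The 25 measured keratin genes had a median of 0.41, or -0.0016 with scaling on the hybridisation controls, and 4 of them were at least 2-fold lower and 1 higher. With the background floor the median was 0, with 3 lower and 0 higher, so a rise of keratin genes is not shown. The 4 lower genes were KRT8, KRT18, KRT19 and KRT20. The higher gene, KRT3, lay below the ceiling with uninfected Jurkat cells.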
